A study of Mus musculus with 32 samples.

How the data were processed

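DNA methylation was profiled in brain, heart, kidney and liver of mice by MeDIP-seq, in which an antibody against 5-methylcytosine (5mC) pulls down methylated DNA fragments that are then sequenced. Each organ was kept either flash-frozen or as FFPE tissue, which is fixed in formalin and embedded in paraffin. The labels list 32 samples in 16 groups of 2, set by organ, preservation and library type. The library type is either the antibody precipitate (16 samples) or the unselected DNA called Input (16 samples). The replicate number of a sample goes with its library date, of which there are 2. Nothing in the labels says that replicates came from separate animals.

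Reads were aligned to the mouse genome mm10 with Bowtie2, counted with featureCounts and analysed with limma, per the submitters' processing notes. Versions, aligner settings, the counted feature (exons or whole gene bodies), strand and the handling of reads with several matches are not given in the sources used here. The deposited table holds log2 counts scaled to library size (CPM) for 27179 genes in 8 columns, 1 per organ and preservation. Its column names give neither the antibody nor a replicate number. The columns were taken as 5mC values because the table was deposited as MeDIP-seq counts, and every result rests on that reading. Whether a column is 1 library or pooled replicates is not given in the sources used here. Each column is called a library. Input values, and so the enrichment of 5mC over Input, were not analysed here. A gene's value can therefore reflect copy number and how well its DNA yields reads as well as methylation.

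The deposited log2 values step in the form limma's voom gives, with 0.5 added to each count. With a tolerance of 1e-04, all values stepped back to whole reads. The reads recovered over the 27179 genes totalled 2164158 to 3699218 per library, and the authors' scaling factors multiplied to 1. Reads recovered in this way were used for depth, shares and floors only. A count of 0 allows up to 3 reads, and shares carry exact Clopper-Pearson 95% intervals. Both cover counting error only, since PCR copies are not independent molecules. Genes were placed by Entrez ID on the RefSeq annotation of GRCm38.p6, the assembly behind mm10, which matched 25275 of 27179 genes (93.0%). Coordinates are those of the whole gene, so exon and intron signal cannot be separated. No genome sequence was used here, so GC content was not checked.

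The planned fit of 8 groups of 2 libraries could not be run on 8 columns. It was replaced by a limma fit of organ plus preservation on the deposited log2 values (R 4.3.3, limma 3.58.1), with 5 coefficients, 3 residual degrees of freedom and 13.1 prior degrees of freedom. Genes with at least 1 CPM in at least 2 libraries were tested, which kept 25982 and removed 1197. The moderated test used a trend of the variance on the mean, and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. The comparisons were each organ against the mean of the other 3, FFPE minus frozen over the 4 organs, and the 6 pairs of organs. Because no group has a second column, the residual measures how far an organ difference changed with preservation, or a preservation difference with organ. Differences within 1 preservation or within 1 organ are values with no test, and the interaction of organ and preservation has no residual degrees of freedom.

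On simulated data with 25982 genes, the organ comparison (simulated for kidney) recovered 70% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, with 13 false calls among unchanged genes. The preservation comparison recovered 86% and 100%, with 19 false calls. The simulated noise was independent between genes, without the library-wide differences in spread found in the real libraries. Changed genes were drawn only from those with a mean at or above the median. The recovery and the false calls therefore do not give error rates for the real libraries.

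The named genes were fixed by a rule. Among called genes with a mean at or above the median of all tested genes, and leaving out predicted models, clone names, small RNAs and pseudogenes, it takes the 10 largest differences in each direction. The organ's libraries had to lie beyond all others, and for preservation every organ had to change the same way. Where the text speaks of the largest rises or falls, the ranking holds only among genes that meet this rule. From each list the rule takes up to 4 called members with the smallest p. These rules, 25 gene lists and the alternatives were fixed before the data were examined. The lists cover cell types of the organs (neurons, astrocytes, oligodendrocytes, microglia, cardiomyocytes, proximal tubule, distal nephron and collecting duct, hepatocytes), cells found in every organ (endothelium, fibroblasts and smooth muscle, leukocytes), and gene families (germline, imprinted, Hox, developmental transcription factor, ribosomal protein, olfactory receptor, vomeronasal receptor, protocadherin, zinc finger, histone, Y, X, mitochondrial and methylation machinery genes). List tests used limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusted by Benjamini-Hochberg over the 25 lists. Limma's fry was planned and run as well. It asks whether a list's genes differ at all, not whether they differ more than other genes. Each list's count is also given with p-values adjusted over the list alone. For liver and brain, a list's median is also given as a percentile among 10000 random lists of like mean signal, which was not planned.

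Alternatives covered no filter on low values, a filter of 4 CPM, quantile normalization, centring on library medians, 1 CPM added before the log, limma without the trend, array quality weights, autosomal genes only, and each library left out in turn. Weights from voom on the recovered reads were added after the data were seen. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The values of 4 genes are not reported here, although the counts of called genes include them.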

Results

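MeDIP-seq signal of 27179 genes was compared between brain, heart, kidney and liver of mice, each kept flash-frozen and as FFPE tissue. The design asks how organs differ in 5mC and how FFPE tissue compares with frozen tissue. A higher value means more precipitated DNA reads on a gene. The values come in 1 column per organ and preservation, 8 in all and each called a library, so no replicate inside a group could be used. Reads counted on these genes numbered 2205597 (frozen brain), 3050175 (FFPE brain), 2641841 (frozen heart), 2386266 (FFPE heart), 3447081 (frozen kidney), 2164158 (FFPE kidney), 3699218 (frozen liver) and 3102535 (FFPE liver). Reads elsewhere in the genome are not included. The median gene had 36 to 63 reads. A gene with 0 reads could hold up to 0.876 CPM (frozen liver) to 1.42 CPM (FFPE kidney). The frozen kidney library had 0 reads on 2999 genes, against 880 to 2380 genes in the others, and 56.2% of its low read counts were even numbers, against 50.3% to 52.7%. The spread of log2 values over genes was narrowest in frozen brain (SD 1.75) and widest in frozen kidney (SD 2.67).

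Brain, heart and liver libraries were each closest to the library of the same organ in the other preservation. Pearson's r across genes, which are not independent replicates, was 0.903 for brain, 0.917 for heart and 0.913 for liver. Kidney stood apart. Frozen and FFPE kidney correlated at 0.862, while frozen kidney was closest to frozen liver (0.871) and FFPE kidney to FFPE heart (0.915). Over all pairs, the median r was 0.908 for the same organ across preservations, 0.880 for different organs in the same preservation and 0.855 for pairs that differed in both. The first principal component held 37.0% of the variance and the second 21.5%.

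**Figure D1:**
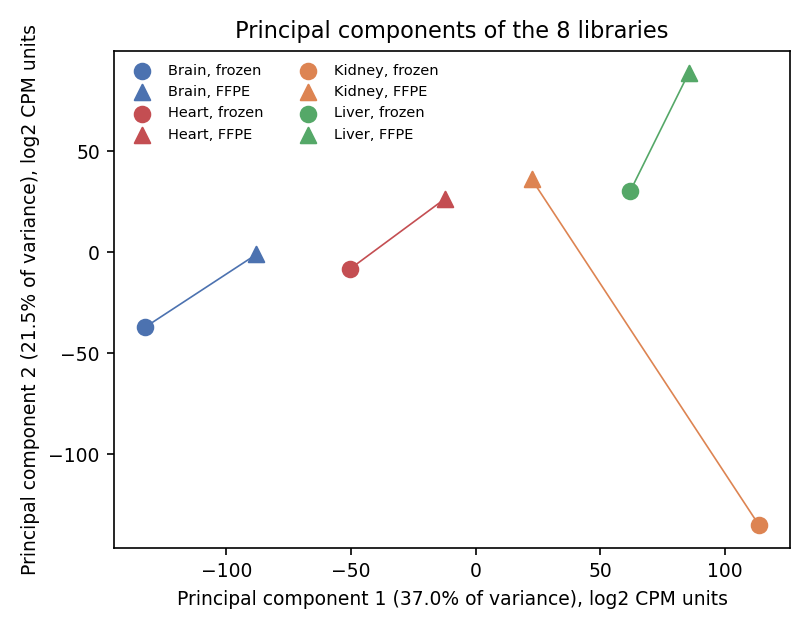
Principal components 1 (37.0% of variance) and 2 (21.5%) of the log2 CPM values, with 1 point per library. Circles are frozen and triangles FFPE libraries, colours mark organs and lines join the libraries of an organ. Frozen kidney lies at 113.7 and -135.3, away from FFPE kidney at 22.5 and 36.2.

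Liver had less 5mC signal than the other organs on most of the listed genes of hepatocytes, its main cell type. Of 50 measured hepatocyte genes, 31 were lower in liver and 1 was higher (39 lower and 1 higher when adjusted over the list alone). The median log2 difference was -1.10, with -1.19 in frozen and -0.91 in FFPE tissue. Alb, which encodes serum albumin, fell by 2.04 ± 0.31 (SE) on the log2 scale, 4.10-fold lower in the 2 liver libraries than in the 6 others (limma, Benjamini-Hochberg adjusted p = 0.000395; Entrez 11657, chromosome 5, 90460870 to 90476602). Fga, a fibrinogen chain, fell by 1.84 ± 0.17 (adjusted p = 2.26e-05), Apob, the protein of low-density lipoprotein, by 1.36 ± 0.19 (adjusted p = 0.00023), Cyp8b1, a bile acid enzyme, by 1.42 ± 0.20 (adjusted p = 0.000224), and Hpx, which binds heme, by 2.88 ± 0.42 (adjusted p = 0.000302). Other secreted liver proteins among the 10 lowest genes were Itih3 (-1.96), Apof (-1.94) and Inhbe (-2.38).

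The gene with the largest rise in liver was Fut11, a fucosyltransferase, at 12.3-fold (log2 3.62 ± 0.30, limma adjusted p = 1.58e-05; Entrez 73068, chromosome 14, 20694968 to 20700197). Gata4, a transcription factor of heart and gut endoderm, was 7.67-fold higher (2.94 ± 0.24, adjusted p = 1.58e-05; Entrez 14463, chromosome 14, 63198914 to 63271712). Coagulation factor gene F12 was 5.97-fold higher (2.58 ± 0.24, adjusted p = 2.26e-05), although hepatocytes make that protein. S1pr5, a sphingosine phosphate receptor, Gal3st1, a sulfatide synthesis enzyme, and Urad, a uric acid pathway enzyme, rose by 3.25, 2.96 and 2.74. Snx20, Prob1, Fam83h and Cfl2 completed the 10, at 3.05, 2.37, 2.35 and 2.22. The largest falls were led by Mab21l2, a developmental gene inside Lrba, at 9.47-fold lower (-3.24 ± 0.29, adjusted p = 1.86e-05), and held Fam172a (-2.67), Tmem30b (-2.59), Nkx2-2os (-2.09) and Osgin1 (-1.93). How reads in the overlap of Mab21l2 and Lrba were counted is not given in the sources used here.

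Zinc finger genes, most of which encode DNA-binding repressors, were higher in liver for 94 and lower for 21 of 363 (107 and 27 adjusted over the list alone), with Zfp13 at 1.59 ± 0.15 and Zfp526 at 1.49 ± 0.14. Imprinted genes, expressed from the copy of 1 parent, were higher for 13 and lower for 2 of 33 (15 and 3 adjusted over the list alone), with Nap1l5 at 1.42 ± 0.17 and Peg3 at 0.99 ± 0.13. Genes of the methylation machinery were higher for 7 and lower for 0 of 16 (8 and 0 adjusted over the list alone), among them Tet3 (0.84) and Mbd3 (0.84). Developmental transcription factor genes were lower for 16 and higher for 4 of 78 (18 and 4 adjusted over the list alone), with Irx2 and Irx5 at 0 to 2 reads in the liver libraries and 14 to 90 in the others. Camera with the preset correlation called the hepatocyte list (adjusted p = 9.73e-14), zinc finger genes (0.00031), imprinted genes (4.41e-05), methylation machinery (0.00197) and developmental transcription factors (0.00032). None of them held with an estimated correlation (adjusted p = 0.122, 0.0806, 0.378, 0.378 and 0.378 with an estimated correlation, in the same order). Among random lists of like mean signal, their medians ranked at percentile 0, 99.2, 70.0, 94.35 and 0, in the same order. The imprinted and methylation machinery medians thus lay inside the middle 95% of such random lists.

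In all, 3056 genes were higher and 1929 lower in liver, of 25982 tested (8460 at an unadjusted p under 0.05). The share of calls that were higher was 61.3%, and 50.6% under quantile normalization and 79.6% with libraries centred on their medians; centring moved the median difference of all genes from -0.10 to 0.10. Of the 3056 higher calls 1266 (41.4%) were kept under quantile normalization, and of the 1929 lower calls 931 (48.3%). Without the frozen liver library 1032 genes were higher and 690 lower, and without the FFPE liver library 975 and 494. The lower count was 1164, 1192, 1132 and 964 without the frozen brain, FFPE brain, frozen heart or FFPE heart library, and 3398 and 3070 without the frozen or FFPE kidney library. Hepatocyte genes called lower numbered 12 without the frozen and 16 without the FFPE liver library, imprinted genes called higher 8 without the FFPE liver library, and zinc finger genes called higher 53 and 59 without the frozen and FFPE liver library. Under quantile normalization 51 zinc finger genes were higher and 14 lower, and 8 imprinted genes higher and 4 lower. Methylation machinery genes called higher numbered 1 without either liver library, 2 without frozen heart, 3 without FFPE heart and 1 under quantile normalization. Developmental transcription factor genes called lower numbered 10 and 6 without the frozen and FFPE liver library. All 19 genes named here by the rule kept their call without any 1 library.

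Brain had less 5mC signal than the other organs on part of the zinc finger and neuronal genes, and more on part of the hepatocyte and developmental transcription factor genes. Of 363 zinc finger genes, 108 were lower and 8 higher in brain (115 and 10 adjusted over the list alone), with a median of -0.28. Zfp219 fell by 2.26 ± 0.17 on the log2 scale (limma adjusted p = 4.64e-06) and Zfp777 by 1.29 ± 0.14. Of 40 neuronal genes, 13 were lower and 2 higher (13 and 3 adjusted over the list alone). Tubb3, a neuronal tubulin, fell by 1.14 ± 0.14 (adjusted p = 0.000149), Dlg4, the postsynaptic scaffold PSD-95, was lower as well (adjusted p = 0.000406), and Ank3, of the axon initial segment, fell by 0.94. Imprinted genes were lower for 12 and higher for 2 of 33 (16 and 2 adjusted over the list alone), with Nap1l5 at -1.24 and Peg3 at -0.73. Methylation machinery genes were lower for 7 and higher for 0 of 16 (9 and 0 adjusted over the list alone), led by Tet3, a 5mC oxidase, at -1.04 ± 0.13 (adjusted p = 0.000149).

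Each organ is set against the mean of the other 3, so a change in 1 organ moves the differences of the others the other way. Results of opposite sign in 2 organs are therefore not independent of each other. This holds for liver and brain on the hepatocyte, zinc finger, imprinted, methylation machinery and developmental transcription factor genes. It also holds for single genes such as Gal3st1 and Prob1 (liver and heart), Snx20 and Nkx2-2os (liver and brain), Tbx2 and Hoxb3 (kidney and brain) and Fam172a (liver and kidney). Hepatocyte genes were higher in brain for 11 and lower for 1 of 50 (16 and 1 adjusted over the list alone), among them Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.45), and Cps1, of the urea cycle (1.08). Developmental transcription factor genes were higher for 21 and lower for 4 of 78 (23 and 5 adjusted over the list alone). The largest falls, however, included 3 of this kind: Tbx3 was 8.23-fold lower (-3.04 ± 0.26, adjusted p = 9.62e-06; Entrez 21386, chromosome 5, 119670534 to 119684724), Hoxb3 6.84-fold lower (-2.77 ± 0.30) and Tbx2 5.31-fold lower (-2.41 ± 0.23). Fam171a2 was 6.79-fold lower (-2.76 ± 0.21, adjusted p = 4.64e-06; Entrez 217219, chromosome 11, 102436981 to 102447677). Snx20 (-2.51), Fbxl8 (-2.29), the small heat shock gene Hspb3 (-2.24) and Igsf8 (-2.22) were also among the largest falls. The largest rise was in Cyp1b1, a cytochrome P450, at 5.64-fold (2.50 ± 0.38, adjusted p = 0.000481; Entrez 13078, chromosome 17, 79706940 to 79715061). Nes, the neural progenitor filament nestin (2.08 ± 0.34), Sox1ot, which overlaps the neural gene Sox1 (2.42), Nkx2-2os, which overlaps Nkx2-2 (1.99), Nr2f2 (1.87), the lymphocyte factor Irf4 (1.85), Ccdc177 (2.08), Rassf10 (1.94), Otud7a (1.93) and Adgrg4 (1.80) were the other 9.

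In brain 2238 genes were higher and 3333 lower (9540 at an unadjusted p under 0.05). The share that was higher was 40.2%, and 47.4% under quantile normalization and 24.7% with centred libraries; centring moved the median difference of all genes from 0.11 to -0.04. Camera called the zinc finger list (adjusted p = 7.4e-07), which held with an estimated correlation (adjusted p = 0.0345), as well as the neuronal (0.000345), imprinted (0.000254), methylation machinery (0.00275), hepatocyte (5.4e-06) and developmental transcription factor (0.000384) lists. The last 5 were lost (adjusted p = 0.298, 0.298, 0.327, 0.298 and 0.327 with an estimated correlation). Among random lists of like mean signal, the brain medians ranked at percentile 0.01, 6.39, 36.9, 11.07, 100 and 98.05, in the order named. In the main fit, the neuronal, imprinted and methylation machinery medians were not extreme among such lists. That fit therefore does not show falls specific to these lists. For neuronal genes the percentile was 19.4 in frozen tissue, 1.59 in FFPE tissue and 1.25 under quantile normalization. Genes higher in brain numbered 92 without the frozen and 302 without the FFPE brain library, 1224 and 1081 without the frozen and FFPE heart library, and 3410 and 4725 without the frozen and FFPE kidney library. Lower genes numbered 654 and 1666 without the frozen and FFPE brain library. Without the frozen and FFPE brain library the lower zinc finger genes numbered 44 and 64 and the higher hepatocyte genes 2 and 1, and without frozen brain the lower neuronal genes numbered 5. Hepatocyte genes called higher numbered 21 and 19 without the frozen and FFPE kidney library, 20 with array quality weights and 19 with voom weights. The lower imprinted genes numbered 4 without frozen brain and 6 under quantile normalization, and the higher developmental transcription factor genes 1, 2 and 11 without frozen brain, FFPE brain and frozen heart. The lower methylation machinery genes numbered 1 and 3 without the frozen and FFPE brain library, 4 without frozen heart, FFPE heart or frozen liver, and 2 under quantile normalization. Of the 19 genes named here by the rule, 16 kept their call without frozen brain and 18 without FFPE brain.

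Part of the cardiomyocyte and germline genes had less 5mC signal in heart than in the other organs. Of 40 cardiomyocyte genes 5 were lower and 0 higher (17 and 1 adjusted over the list alone), with a median of -0.42, which was -0.47 in frozen and -0.41 in FFPE tissue. Myh6 and Myh7, the cardiac myosin heavy chains, fell by 0.78 ± 0.13 (limma adjusted p = 0.00717) and 0.73 ± 0.14 (adjusted p = 0.0151). Casq2, the calcium store protein of heart muscle, fell by 0.95 and Ttn, the giant sarcomere protein titin, by 0.77. The fifth was Gata4, at -1.01 (adjusted p = 0.0388), which mirrors its rise in liver: it had 46 and 61 reads in frozen and FFPE heart, 29 and 40 in kidney, 72 and 113 in brain, and 533 and 410 in liver. Of 43 germline genes 9 were lower and 0 higher (21 and 0 adjusted over the list alone), among them Dazl, an RNA-binding protein of germ cells (-1.58 ± 0.22, adjusted p = 0.00285), Zfp42, a pluripotency marker (-1.02 ± 0.14), and Sycp1, of the meiotic synaptonemal complex (-1.21). Imprinted genes were lower for 4 and higher for 0 of 33 (12 and 0 adjusted over the list alone), led by Cdkn1c, a growth-restraining cell cycle inhibitor (-1.17, adjusted p = 0.00376). The endothelial genes Cdh5 and Kdr were also lower (-0.86 and -0.85), 2 of 18 measured (3 adjusted over the list alone).

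The largest falls in heart were in Klf2, a transcription factor of the vessel lining, at 6.15-fold lower (-2.62 ± 0.25, limma adjusted p = 0.000131; Entrez 16598, chromosome 8, 72319062 to 72321654), Gal3st1 at 6.12-fold lower (-2.61 ± 0.25, adjusted p = 0.000131) and Sox9, a transcription factor of cartilage and glia, at 4.82-fold lower (-2.27 ± 0.24, adjusted p = 0.000351). Prob1 (-2.17), Prr23a2 (-1.83), the testis histone gene H2bc1 (-1.70), Skida1 (-1.70), the tumour suppressor gene Hic1 (-1.65), Dazl and Myadm (-1.54) followed. The rises were smaller, from Gpr108 and Nacad (1.47 each) and Stard10 (1.36) to Map1a, a microtubule protein (0.98 ± 0.17, adjusted p = 0.00849), and Lrrc75b (0.97), with Tob1, Yars, Gpc2, Dbndd2 and Nek9 between. In all, 42 genes were higher and 513 lower in heart (3804 at an unadjusted p under 0.05). The higher share was 7.57%, and 32.6% under quantile normalization. Camera called the cardiomyocyte, germline, imprinted and endothelial lists (adjusted p = 1.11e-08, 1.09e-11, 1.27e-08 and 0.00114), and lost all of them (adjusted p = 0.0683, 0.0683, 0.188 and 0.362 with an estimated correlation).

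The heart counts depended on single libraries. Higher genes numbered 0 without either heart library, 219 and 710 without the frozen and FFPE kidney library, 26 and 27 without the frozen and FFPE brain library, and 22 and 16 without the frozen and FFPE liver library. Lower genes numbered 4 and 6 without the frozen and FFPE heart library, 826 and 1393 without the frozen and FFPE kidney library, 322 without FFPE brain, and 282 and 158 without the frozen and FFPE liver library. Cardiomyocyte genes called lower numbered 0 without either heart library, 1 and 3 without FFPE and frozen liver, 3 without FFPE brain, and 11 without either kidney library. Germline genes called lower numbered 0 without either heart library, 4 without FFPE liver and 18 without FFPE kidney. Imprinted genes called lower numbered 0 without either heart library, 2 without FFPE liver, and 9 and 11 without frozen and FFPE kidney, and the endothelial genes 0 without either heart library. Cardiomyocyte genes called lower numbered 3 with no filter, 8 with centred libraries and 11 with array quality weights, and germline genes 16 with array quality weights. Imprinted genes numbered 9 with centred libraries or array quality weights, 8 with autosomal genes only, and 7 with voom weights or 1 CPM added. Of the 20 genes named by the rule, 4 kept their call without either heart library, among them Klf2, Gal3st1 and Prob1, and 12 to 20 kept it without any 1 of the other libraries.

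Kidney had far more 5mC signal on many of the Hox genes, the clustered transcription factors that set position along the body axis. Of 38 Hox genes 19 were higher and 0 lower (27 and 0 adjusted over the list alone), with a median log2 difference of 2.71 in frozen and 2.66 in FFPE tissue. Hoxd3 had 555 and 259 reads in frozen and FFPE kidney and 5 to 18 in each of the other 6 libraries (5.12 ± 0.44, limma adjusted p = 7.38e-05; Entrez 15434, chromosome 2, 74711993 to 74748271). Hoxd12 (5.11 ± 0.66), Hoxc6 (4.12 ± 0.53) and Hoxd4 (3.77 ± 0.44) followed. Called genes lay in all 4 clusters, with 6 of 11 tested genes in Hoxa, 3 of 9 in Hoxb, 5 of 9 in Hoxc and 5 of 9 in Hoxd. Several Hox genes overlap, and of 32 that remain when 1 gene per overlapping stretch is kept, 16 were higher. Pax2, a transcription factor needed to form the kidney, was 4.57-fold higher (2.19 ± 0.27, adjusted p = 0.00194; Entrez 18504, chromosome 19, 44746601 to 44838269).

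Protocadherin genes, clustered genes for neuronal adhesion proteins, were higher in kidney for 11 and lower for 0 of 58 (36 and 1 adjusted over the list alone), among them Pcdha11 at 0.98 ± 0.17. Apoe, a lipid carrier protein, was 2.90-fold higher (1.53 ± 0.21, limma adjusted p = 0.00347; Entrez 11816, chromosome 7, 19696244 to 19701310). Other rises were Pnmal2 (2.06), Hoxb3 (1.94), Hspa2 (1.87), Foxc1, a transcription factor of the eye and kidney (1.82), Fam172a (1.54), Tbx2 (1.35) and Ddx28 (1.30). The falls were led by Alox12e (-1.59), Birc5, the cell division protein survivin (-1.51), and Smad3, which carries TGF-beta signals (-1.40 ± 0.21, adjusted p = 0.00639), with Cbx5, Fam107b, Msh5, Fzd4, Drd1, Klhl6 and Creb3l2 from -1.39 to -1.25. Gata4 fell by 1.82 ± 0.24 (adjusted p = 0.0031), to which its rise in liver adds. Of 27 proximal tubule genes 0 were higher and 0 lower (0 and 0 adjusted over the list alone, and 0 and 3 in limma at an unadjusted p under 0.05). Their median was -0.25, with -0.01 in frozen and -0.28 in FFPE tissue. Of 30 distal nephron and collecting duct genes 2 were higher, Pax2 and Hoxb7, and 0 lower (5 and 7 adjusted over the list alone). The list's median of 0.02 turned negative under quantile normalization, and it was 0.20 in frozen and -0.11 in FFPE tissue.

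In kidney 233 genes were higher and 147 lower (4843 at an unadjusted p under 0.05). Camera called the Hox (adjusted p = 4.78e-26), protocadherin (1.6e-20) and proximal tubule lists (0.0238), and lost all 3 (adjusted p = 0.267, 0.267 and 0.532 with an estimated correlation). Hox genes called higher numbered 7 without frozen kidney, 9 without frozen heart, 12 without FFPE liver, 12 with no filter and 11 with array quality weights. Protocadherin genes called higher numbered 0 without frozen kidney or frozen heart, 1 without FFPE heart, frozen brain or FFPE liver, 2 without frozen liver and 26 without FFPE kidney, and 4 under quantile normalization, 5 with no filter, 1 with array quality weights and 19 with voom weights. Of all genes, without the frozen and FFPE kidney library 24 and 1522 were higher and 60 and 2264 lower, and without the frozen and FFPE heart library 21 and 71 were higher and 3 and 15 lower. Without the frozen brain library 81 were higher and 16 lower, without FFPE brain 88 were lower, and without the frozen and FFPE liver library 77 and 65 were higher and 41 and 16 lower. Of the 19 genes named here by the rule, 7 kept their call without frozen kidney, 2 without frozen heart and 11 to 19 without any 1 of the other libraries. Pax2 and Apoe kept it without any 1 library.

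**Figure D2:**
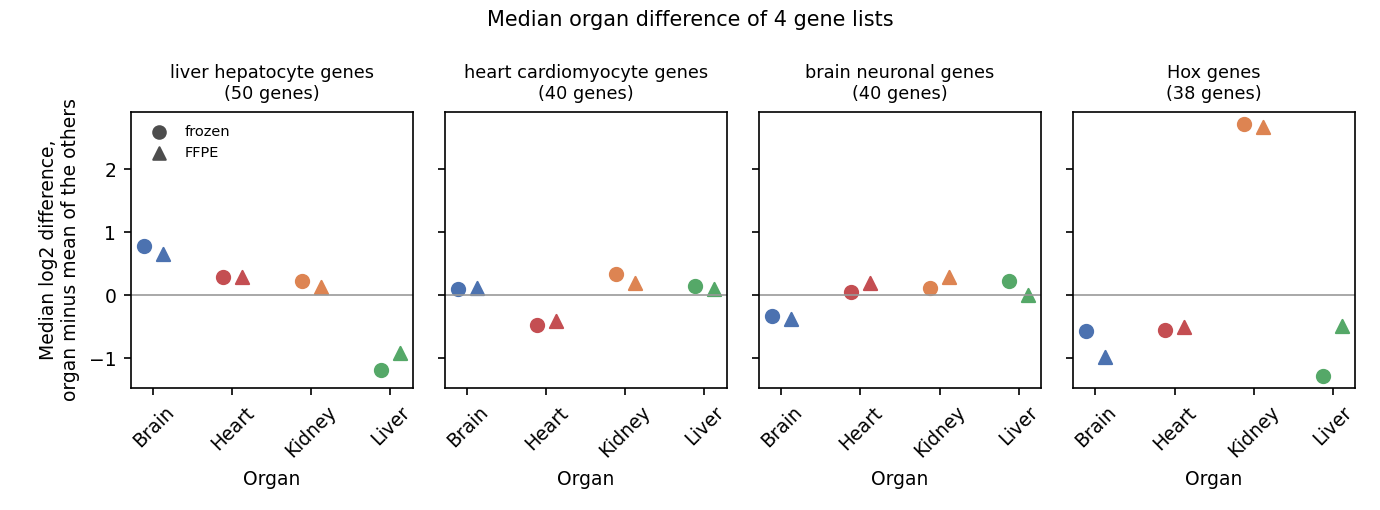
Median log2 difference of an organ against the mean of the other 3 for the genes of 4 lists, with circles for frozen and triangles for FFPE libraries (1 library per point, no error bar). Hepatocyte genes were lowest in liver (-1.19 frozen, -0.91 FFPE), cardiomyocyte genes in heart (-0.47, -0.41) and neuronal genes in brain (-0.33, -0.38), and Hox genes were highest in kidney (2.71, 2.66); in liver the medians of the neuronal and cardiomyocyte lists turned negative under quantile normalization.

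The organ calls in limma depended on the trend of variance on mean signal. Without it, limma called 0 genes higher or lower in each of the 4 organ comparisons, with 7872 (brain), 2851 (heart), 3471 (kidney) and 7101 (liver) genes at an unadjusted p under 0.05. Between pairs of organs, brain and liver differed in 7405 genes (3295 higher in brain, 4110 in liver), brain and kidney in 4171 (1665 and 2506), heart and liver in 3133 (856 and 2277), heart and kidney in 643 (89 and 554), kidney and liver in 493 (196 and 297), and brain and heart in 445 (135 and 310). Brain and heart differed in 23, 98, 5 and 1 genes without frozen brain, FFPE brain, frozen heart and FFPE heart, 2167 and 2160 without frozen and FFPE kidney, and 225 and 236 without frozen and FFPE liver. Brain and kidney differed in 483, 1883, 2467 and 6926 without frozen brain, FFPE brain, frozen kidney and FFPE kidney, and brain and liver in 3014, 3862, 4045 and 4117 without frozen brain, FFPE brain, frozen liver and FFPE liver. Heart and kidney differed in 0, 34, 275 and 3767 without frozen heart, FFPE heart, frozen kidney and FFPE kidney. Heart and liver differed in 623 and 931 without frozen and FFPE heart, 5415 and 5386 without frozen and FFPE kidney, and 1380 and 977 without frozen and FFPE liver. Kidney and liver differed in 220 and 216 without frozen and FFPE heart, 2593 without FFPE kidney, and 75 and 77 without frozen and FFPE liver.

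FFPE tissue gave organ differences that ran with those of frozen tissue to a degree that varied by organ. Across 25982 genes, Pearson's r (Spearman's rho) between the frozen and the FFPE difference was 0.601 (0.648) for brain, 0.399 (0.495) for liver, 0.222 (0.313) for heart and 0.132 (0.157) for kidney. Each is a value with no test, since each side is 1 library against 3 and genes are not independent. The difference had the same sign in both preservations for 76.9%, 71.2%, 64.1% and 57.3% of genes, in the same order. In brain 3298 genes were higher by at least 1 on the log2 scale in both preservations, where independent lists would share 1108, and in liver 1891 were lower in both, where independent lists would share 780. In kidney 285 were higher and 942 lower in both, against 110 and 407 for independent lists, and in heart 733 and 294, against 248 and 72.4. The frozen and FFPE differences use separate libraries. A spread of values that an organ shares in both preservations can still raise the overlaps and shared signs. The SD of log2 values was 1.75 (frozen) and 2.02 (FFPE) in brain, and 2.49 and 2.60 in liver. The excess over independent lists therefore does not by itself show shared differences in 5mC. Pearson's r for kidney was 0.0269 without FFPE brain, 0.0867 without frozen brain and 0.207 without FFPE liver, and for heart 0.139 without FFPE liver.

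FFPE tissue differed from frozen tissue at 352 genes, 161 higher and 191 lower (2773 at an unadjusted p under 0.05), and 344 of them differed in the same direction in all 4 organs, which the fit favours by calling genes whose difference changes little between organs. Over all 25982 genes, the preservation differences of 2 organs correlated at 0.0719 (heart and kidney) to 0.322 (brain and heart). The 15 genes of the mitochondrial genome were lower for 10 and higher for 0 (15 and 0 adjusted over the list alone), with a median of -1.29. ND3 and ND4L, subunits of respiratory complex I, fell by 2.56 ± 0.32 (limma adjusted p = 0.000243) and 1.52 ± 0.24 (adjusted p = 0.00193); they were also the 2 that were lower in FFPE liver (-0.66 and -0.12), where the other 13 were higher. Mitochondrial genes took 8.66% of reads in frozen brain (95% interval 8.62 to 8.70) and 1.76% in FFPE brain (1.75 to 1.78), 7.24% and 2.72% in heart, 2.68% and 0.885% in kidney, and 1.35% and 1.64% in liver, so liver did not share the direction. Camera called this list (adjusted p = 9.78e-25), and lost it (adjusted p = 0.753 with an estimated correlation). The correlation estimated between its genes was 0.980, so the 15 genes moved together and their calls are not separate observations. The mitochondrial genes called lower numbered 2 without any 1 of the brain or heart libraries, 15 without either liver library, and 2 with no filter on low values.

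**Figure D3:**
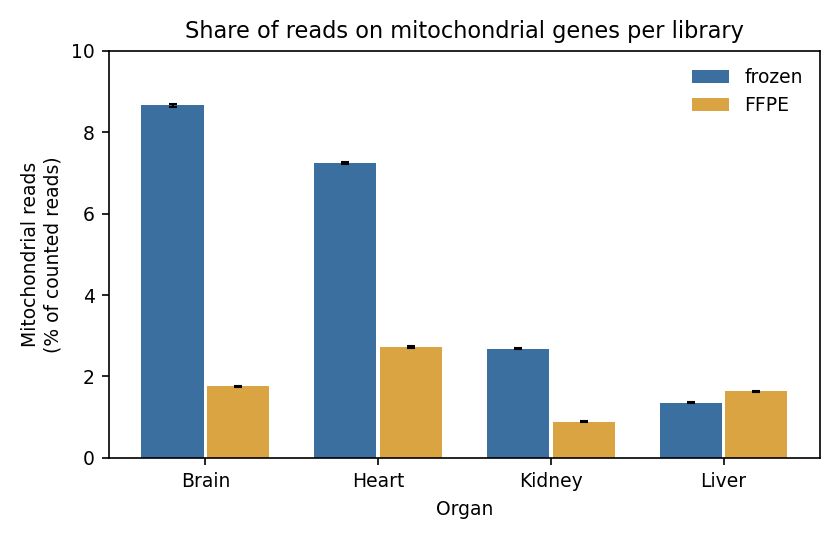
Percent of counted reads on mitochondrial genes in each of the 8 libraries, as bars from 0 with exact 95% binomial intervals for counting error. FFPE was below frozen in brain (1.76% against 8.66%), heart (2.72% against 7.24%) and kidney (0.885% against 2.68%) and above it in liver (1.64% against 1.35%).

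Several of the nuclear genes that differed between preservations lay side by side. Glo1, the glyoxalase that detoxifies methylglyoxal, was 3.52-fold higher in FFPE tissue (log2 1.82 ± 0.15, limma adjusted p = 2.53e-06; Entrez 109801, chromosome 17, 30592861 to 30612659), higher in 4 of 4 organs. The neighbours given here were chosen after their values were seen. Dnah8, a sperm tail dynein, was 3.21-fold higher (1.68 ± 0.12, adjusted p = 5.21e-07) and Btbd9 2.17-fold higher (1.12 ± 0.12, adjusted p = 6.24e-05). 1700097N02Rik, between Glo1 and Dnah8, was 3.96-fold higher (1.99 ± 0.27, adjusted p = 0.000589). Gm6402, which lies inside Btbd9, was not called (0.22 ± 0.16, adjusted p = 0.690). Glp1r, the incretin receptor, missed the threshold (0.73 ± 0.18, adjusted p = 0.0533), and Zfand3 and Umodl1 on either side differed by 0.04 ± 0.15 and 0.03 ± 0.16. Among the falls, Sprr2a2, a cornified envelope protein, was 9.07-fold lower (-3.18 ± 0.27, adjusted p = 3.98e-06; Entrez 100303744, chromosome 3, 92250647 to 92257304) and Tcp10c 4.88-fold lower (-2.29 ± 0.20, adjusted p = 4.07e-06; Entrez 100041352, chromosome 17, 13354572 to 13377223). Both carry the names of gene families, so their read counts may be uncertain. No sequences of the copies were used here.

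**Figure D4:**
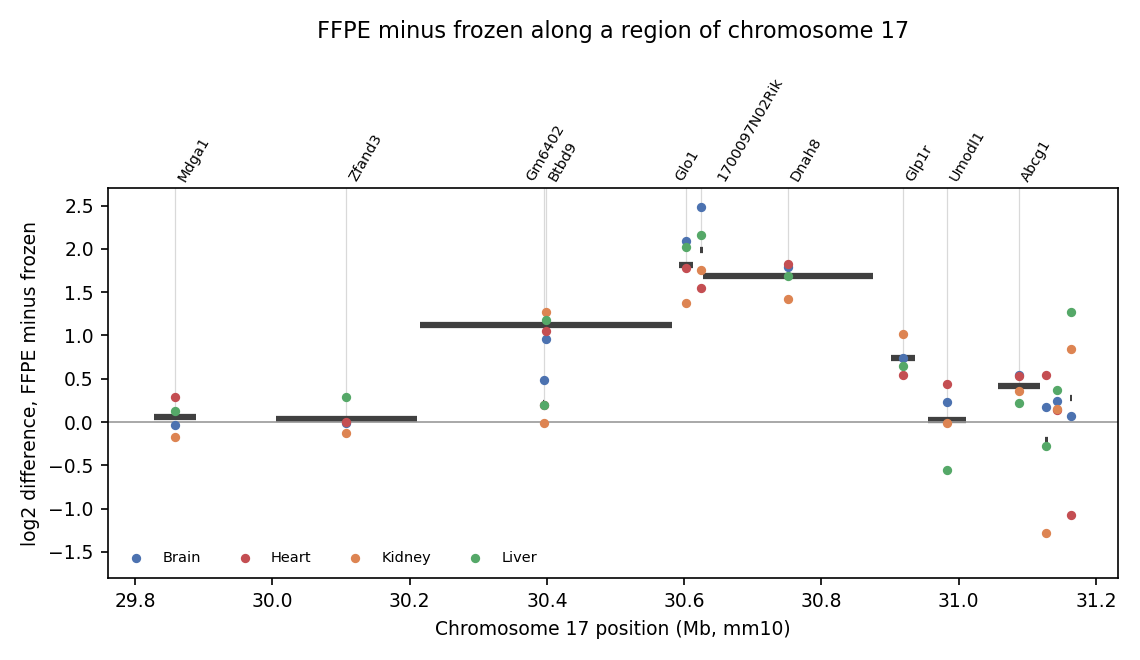
FFPE minus frozen log2 difference along chromosome 17 (mm10, in Mb), with bars spanning each gene at its mean over the 4 organs and points for the organs. Btbd9 (1.12), Glo1 (1.82), 1700097N02Rik (1.99) and Dnah8 (1.68) lie above 0 in all 4 organs, between Zfand3 (0.04) and Umodl1 (0.03). So does Glp1r (0.73), which was not called, but not Gm6402 (0.22).

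The other rises in FFPE tissue named by the rule were led by Ndufc2, of respiratory complex I, at 5.08-fold (2.35 ± 0.31, limma adjusted p = 0.000398). Las1l, of ribosome assembly (2.22), the cell cycle kinase Cdk4 (2.21), the mitochondrial phosphate carrier Slc25a3 (2.02) and the splicing helicase Ddx39b (2.01) followed. Ccdc117 (1.98 ± 0.18, adjusted p = 1.01e-05), Ppp2r2d (1.79), the pheromone receptor gene Vmn2r29 (1.76 ± 0.13, adjusted p = 9.8e-07) and Cnih1 (1.76) were the rest. Some predicted models and pseudogenes, which the rule leaves out, rose by more, among them Gm21370 (4.89) and Rps12-ps12 (3.57). The other falls named by the rule were Iqcc (-1.61), Rimbp3 (-1.35), the DNA sensor Aim2 (-1.28), Duxbl1 (-1.28), the chemokine receptor gene Cxcr4 (-1.24) and Zfp981 (-1.24). Vomeronasal receptor genes were lower for 10 and higher for 1 of 338 (15 and 1 adjusted over the list alone), which camera called (adjusted p = 2.18e-05) and lost (adjusted p = 0.874 with an estimated correlation); the list's median FFPE minus frozen difference was -0.98 in brain, -0.91 in heart and -0.11 in liver but 0.18 in kidney, where 179 of the 338 were higher in FFPE. Vmn1r245 had 16 to 25 reads in each frozen library and 0 in each FFPE library. The vomeronasal genes called lower numbered 1 without frozen brain or frozen heart, 2 without FFPE heart or frozen liver, and 3 without FFPE brain or FFPE liver, and 3 with a filter of 4 CPM and 16 with array quality weights. Without 1 library the count of higher genes was 105 (FFPE brain), 89 (frozen heart), 85 (FFPE heart), 102 (frozen liver) and 95 (FFPE liver), and that of lower genes 91 (frozen brain), 122 (FFPE brain), 83 (frozen heart), 102 (FFPE heart), 91 (frozen liver) and 112 (FFPE liver). Of the 20 genes named by the rule, 15 (without frozen brain) to 20 (without FFPE kidney) kept their call. Limma without the trend called 15 genes higher and 24 lower (2294 at an unadjusted p under 0.05). Preservation cannot be told apart from the animals or the handling behind the frozen and the FFPE tissue.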

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

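All tests weighed here except those of overlapping Hox genes and of a wider kidney spread were chosen only after the results were seen, and the test of neighbouring genes was first set for all pairs together and divided by gene name after the counts were seen.

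The mitochondrial genes differed between preservations in opposite directions in different organs. The median FFPE minus frozen log2 difference of the 15 genes was -2.40 in brain, -1.35 in heart and -1.63 in kidney, with 0 genes higher in FFPE, and 0.44 in liver, with 13 of 15 genes higher. The difference between organs was not tested, because each organ has 1 library per preservation. Dixon's test at its 95% critical value for 4 values found 0 far from the others in 32 groups, which were the 4 organ differences of a named gene or a measure of the 4 libraries of 1 preservation, although frozen kidney stood apart in its principal components. The named genes had been chosen for changing the same way in every organ, and with 4 values the test has little power. Its result therefore says little about outlying organs or libraries.

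Of the genes that differed between FFPE and frozen tissue, 47 pairs were neighbours on a chromosome that changed the same way without overlapping, where 10000 random placements of the calls gave a median of 1 and at most 7 (permutation p = 1e-04, the smallest they can give). Only 8 splits of the libraries part every organ as the real one does, too few for a share under 0.05; the real one gave 352 genes and the highest of the others 0, and of the 27 further splits 3 could not be fitted and the highest gave 5. Placement of reads among near-identical copies cannot be told apart for the 42 pairs of related or unnamed genes, nor for 5 pairs of neighbours with unrelated names (random median 0, permutation p = 3e-04), since no sequences of the copies were used here. Inherited copy-number differences between the mice behind the frozen and the FFPE tissue may account for part of the calls, as a hypothesis: the segment from Btbd9 to Dnah8 is known to be duplicated in some inbred strains (though Gm6402, inside Btbd9, differed by 0.22), and 36 of the 191 lower genes had at most 3 reads in every FFPE library. Clustering alone does not single this out, since brain calls also made 999 neighbouring pairs against a random median of 548, and fixation, handling and the animals stay open because the design joins them.

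Brain calls ran with the spread of values, which was narrowest in frozen brain, as the median log2 CPM was 3.90 for higher and 6.13 for lower calls. A narrower spread of values, taken by itself, is argued against as the whole cause. Quantile normalization gives each library the same spread, and it left 68.7% of the brain calls called in the same direction. For higher and lower calls apart the shares were 78.3% and 62.3%. In liver, where they were 41.4% and 48.3%, the same test does not argue against the spread as the source of the calls. The rest of the brain calls may depend on the spread. Quantile normalization keeps the order of genes in a library, so it cannot speak to antibody enrichment that changes this order. Input was not analysed here. The difference between organs stays open as the biological explanation. Each organ has 2 libraries, and no test here separates that difference from the way brain DNA was prepared.

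Hox genes were higher in kidney, whose frozen library stood apart from the others. That library as the sole cause is argued against by a median of 2.66 in FFPE tissue alone. Reads counted for several overlapping genes could raise the number of called genes. With 1 gene per overlapping stretch kept, 16 of 32 were higher, and all 4 clusters still held a called gene. The clusters lie on separate chromosomes and the kept gene still holds any shared reads. The count of clusters could therefore hardly have come out otherwise, and no conclusion is drawn from it. A wider spread of kidney values is argued against by a median of 2.94 under quantile normalization, with 1.11 as its margin (the interquartile range over 2). A difference in Hox methylation between organs may remain as a hypothesis, as may one in the animals or in the part of the kidney sampled, none of which was tested.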

How the results depend on the processing

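The voom weights and the additive fit of organ and preservation were chosen only after the data were seen, and the other alternatives were planned. Of 344 named gene results, 344 kept their call with 1 CPM added before the log, 341 of 342 with a filter of 4 CPM, 337 with voom weights, 333 with libraries centred on their medians, 321 with array quality weights, 320 with no filter on low values, 315 of 315 with autosomal genes only, 294 under quantile normalization and 5 without the trend. Leaving out 1 library kept 211 (frozen heart) to 344 (FFPE kidney). Under quantile normalization 3 liver results reversed, of which Cspg4 (-0.0303) and Tet1 (-0.0926) are given here. The causes were not tested. No paired analysis was possible because the columns carry no replicate number, so the replicate block was not run, although the fit compares FFPE with frozen tissue within each organ. For the same reason a library date batch could not be examined. Count models were not run, since the deposited values are log2, nor were values with Input subtracted, which were not used here, nor the correlation over genes called in either preservation, since neither preservation alone has a test. Where 1 library is left out, the lone library of that organ is assumed to vary like the others. Depth limits low genes: a gene with 0 reads could hold up to 1.42 CPM in the shallowest library.

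Without the trend, limma called 0 genes higher and 0 lower for brain, heart, kidney and liver, 15 higher and 24 lower for FFPE minus frozen, 2290 between brain and liver, and 0 for each of the other 5 pairs. With array quality weights, brain had 3877 genes higher, heart 317 higher and 1144 lower, kidney 66 higher and 21 lower, FFPE 297 higher and 287 lower, and the pairs brain and heart 2838, heart and liver 4942, and kidney and liver 245. With voom weights, brain had 3969 higher, heart 219 higher and kidney 858 higher, heart and kidney differed in 1146 genes and kidney and liver in 1194. Under quantile normalization, heart had 168 higher and liver 1324 higher, and brain and heart differed in 1775, heart and liver in 1647, and kidney and liver in 172. Centred libraries gave 859 lower in heart, 4832 higher and 1240 lower in liver, 700 between brain and heart, 1054 between heart and kidney and 1023 between kidney and liver. With 1 CPM added, heart had 89 and kidney 359 higher, and brain and heart differed in 812. With no filter, heart had 24 higher, kidney 107 higher and 51 lower, and brain and heart differed in 291. With an estimated correlation between genes, the lists past the threshold went from 15 to 1 in brain, 9 to 0 in heart, 11 to 0 in kidney, 11 to 0 in liver and 3 to 0 for FFPE minus frozen. Fry called the hepatocyte list in liver (adjusted p = 0.013) and the cardiomyocyte and germline lists in heart (0.0103 each). It also called the Hox list in kidney (0.0387), among other lists. Fry did not call the protocadherin list in kidney (0.0542), or the mitochondrial and vomeronasal lists for FFPE minus frozen (0.439 each). Since fry does not compare a list with other genes, its calls do not show that a list stands out.

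Leaving out each library in turn gave 92 to 4725 genes higher and 654 to 4433 lower in brain, 0 to 710 higher and 4 to 1393 lower in heart, 21 to 1522 higher and 3 to 2264 lower in kidney, 975 to 3864 higher and 494 to 3398 lower in liver, and 85 to 221 higher and 83 to 252 lower in FFPE tissue. For the pairs it gave 1 to 2167 (brain and heart), 483 to 6926 (brain and kidney), 3014 to 10297 (brain and liver), 0 to 3767 (heart and kidney), 623 to 5415 (heart and liver) and 75 to 2593 (kidney and liver).

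The correlation of organ differences between frozen and FFPE tissue was 0.566 with no filter, 0.678 with a filter of 4 CPM, 0.540 under quantile normalization and 0.671 with 1 CPM added for brain; 0.301 with 4 CPM and 0.336 with 1 CPM added for heart; 0.201 with 1 CPM added for kidney; and 0.484, 0.313 and 0.543 with 4 CPM, quantile normalization and 1 CPM added for liver. Leaving out each library gave 0.538 to 0.602 for brain, 0.139 to 0.252 for heart, 0.0269 to 0.207 for kidney and 0.285 to 0.462 for liver.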

Other observations

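The genes named individually here outside the lists were chosen after their values were seen, and the counts of genes near 0 reads and of pseudogenes were chosen only after the preservation results were seen.

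Olfactory receptor genes, the large family for smell, were higher in brain for 105 and lower for 3 of 1104 (0 and 0 adjusted over the list alone) and lower in liver for 110 and higher for 13 (42 and 7 adjusted over the list alone). Their median was 1.30 in brain (adjusted p = 0.298 with an estimated correlation) and -0.76 in liver (adjusted p = 0.378 with an estimated correlation). Of all 25982 tested genes, 2238 were higher in brain, a share close to that of the olfactory receptor list, and 1929 were lower in liver. Since each organ is set against the mean of the others, the brain and liver results of this list and of the leukocyte list are not independent of each other. The higher count in brain was 0 without frozen brain and 2 without FFPE brain, 34 and 20 without frozen and FFPE heart, and 208 and 429 without frozen and FFPE kidney. In liver the lower count was 60 and 26 without frozen and FFPE liver, 59 and 51 without frozen and FFPE brain, 49 and 44 without frozen and FFPE heart, and 277 and 197 without frozen and FFPE kidney. Of olfactory receptor genes, 41 were higher in brain under quantile normalization, 62 with a filter of 4 CPM, 243 with 1 CPM added, 274 with array quality weights and 305 with voom weights, and 31 were lower in liver under quantile normalization and 43 with voom weights. Leukocyte genes were higher in brain for 5 and lower for 1 of 26 (5 and 1 adjusted over the list alone), with Ptprc, the leukocyte antigen CD45, at 1.65, and lower in liver for 4 and higher for 0 (6 and 0 adjusted over the list alone), with Ptprc at -1.14. Camera lost both (adjusted p = 0.298 in brain and 0.378 in liver with an estimated correlation). The higher leukocyte genes in brain numbered 1 without either brain library, 3 and 2 without frozen and FFPE heart, 3 without FFPE liver and 11 without FFPE kidney, 8 with array quality weights and 9 with voom weights. The lower ones in liver numbered 0 without FFPE liver, 2 without frozen brain, FFPE brain or frozen heart, 1 without FFPE heart, and 9 and 7 without frozen and FFPE kidney, and 2 with voom weights.

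Oligodendrocyte genes were lower in brain for 4 and higher for 1 of 15 (4 and 1 adjusted over the list alone), with the myelin genes Cldn11 at -1.13 and Mbp at -0.68 and with Ermn higher, and the list's median of -0.17 turned positive under quantile normalization. Without the frozen brain library 0 were lower and 0 higher, and under quantile normalization 2 and 2. Astrocyte genes gave 0 calls of 14 in brain in limma (0 adjusted over the list alone, and 4 higher and 4 lower at an unadjusted p under 0.05), while quantile normalization gave 4 higher and 2 lower, array quality weights 3 and 4, and centred libraries 0 and 4. Microglia genes gave 1 higher and 0 lower of 12 (1 and 0 adjusted over the list alone), and genes of fibroblasts and smooth muscle 1 higher and 0 lower of 16 in brain (0 and 0 adjusted over the list alone). Ribosomal protein genes were lower in brain for 8 and higher for 0 of 85 (0 and 0 adjusted over the list alone; camera adjusted p = 0.0236, and adjusted p = 0.506 with an estimated correlation), and histone genes for 1 and 0 of 33 (0 and 0 adjusted over the list alone). Ribosomal protein and histone genes were called less often than all 25982 tested genes, of which 2238 were higher and 3333 lower in brain. The lower ribosomal protein genes numbered 0 without frozen brain or frozen heart, 2 without FFPE brain, 5 without FFPE liver and 13 without FFPE kidney. Under quantile normalization they numbered 20. X chromosome genes were higher in liver for 60 and lower for 37 of 1092 (37 and 15 adjusted over the list alone). Both are smaller shares than the 3056 higher and 1929 lower of all 25982 tested genes. The median of the X chromosome genes was -0.28, which turned positive under quantile normalization. The higher X chromosome genes in liver numbered 18 and 9 without frozen and FFPE liver and 38 without frozen heart, and the lower ones 15 and 4 without frozen and FFPE liver, 23 and 20 without frozen and FFPE brain, 23 and 16 without frozen and FFPE heart, and 88 and 96 without frozen and FFPE kidney, and 12 under quantile normalization. The list of 9 Y chromosome genes gave 0 calls in limma in every comparison, with 2 higher in FFPE tissue at an unadjusted p under 0.05 and 0 in each organ comparison, while 3 of all 101 tested genes on Y were called for FFPE minus frozen. Of the lists, 16 had no called gene for FFPE minus frozen.

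Several genes had reads in each frozen library and nearly none in each FFPE library. Skint3 and Skint4, of a thymus and skin family, had 18 to 40 reads in each frozen library and 0 in each FFPE library. Smok2a, a sperm motility kinase gene, had 130 to 217 reads in each frozen library and 0 to 2 in each FFPE library, although how reads shared with close relatives were placed is not given in the sources used here. In all, 36 of the 191 genes lower in FFPE had at most 3 reads in every FFPE library, and 10 of these had at least 20 in every frozen library. In the other direction, the X-linked pseudogene Rps12-ps12 had 236 to 396 reads in each FFPE library and 13 to 57 in each frozen library. Pseudogenes made up 15.9% of the 352 called genes (56) and 2.93% of the others (Fisher's exact test, two-sided, odds ratio 6.26, p = 6.1e-24). Genes are not independent. Among heart calls the share was 6.31%, against 3.04% of the others (odds ratio 2.15), and in brain, kidney and liver it was lower among calls than among the others. Genes without a RefSeq match, 17.9% of the 352 and 6.25% of all tested genes, counted as not pseudogenes.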
